A study of Arabidopsis thaliana with 16 samples.

How the data were processed

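Total RNA of roots and leaves from 25-day-old plants, grown in Oil-Dri pellets with Hoagland nutrients, was made into stranded mRNA libraries per the labels' protocols. The deposited values are raw read counts per gene, 1 file per library with 32678 loci and 5 closing lines that name no gene. Per the submitters' processing notes the authors used cutadapt 1.2.1, TopHat2 2.0.9, HTSeq 0.5.4p3, R 3.1.1, edgeR and limma with the TAIR10 build; the role and settings of each, including the strand setting of the counts, are not given in the sources used here. Multiply aligned reads were set aside in 1 of the closing lines, so genes with near-identical copies have lowered and uncertain counts, and overlapping or antisense genes are uncertain too.

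The lines naming no gene held 8.57 to 10.26% of root and 7.26 to 7.77% of leaf reads and were left out of library sizes and tests. The remaining depth was 20139794 to 31405117 reads in roots and 9465995 to 15530134 in leaves, so low transcripts are measured less precisely in leaves. The libraries of a group differed by a chi-square of 4.32 to 40.5 per degree of freedom, more than counting error gives, and each library was counted as 1 replicate. Symbols and coordinates came from the TAIR10.1 gene table, in which 31912 of the loci were matched by locus identifier.

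Groups follow the sample labels. For the 8 leaf libraries the file names give another genotype than the labels; the labels were kept. The descriptions of the 2 EXS34 replicate 2 samples number them 1, and they were taken as replicate 2 from their titles; their counts differ from those of replicate 1 (chi-square per degree of freedom 27.5 in roots and 12.5 in leaves). The test was fixed before the data were examined: per tissue, all 8 libraries in 1 fit with edgeR 4.0.16 in R 4.3.3, filterByExpr (minimum count 10, minimum total 15), TMM scaling, robust quasi-likelihood fit and test, no block, and Benjamini-Hochberg adjustment with a threshold of 0.05. This left 20597 genes in roots and 18548 in leaves. The comparisons were the 6 pairs of genotypes in each tissue and, in roots, the mean of both EXS lines against KO and against Compl. Standard errors are the log2 fold change divided by the square root of the F statistic. Tissue differences were tested as interactions in 1 fit of all 16 libraries over 21351 genes.

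A set of 29 gene lists with 371 entries was also fixed then and tested with camera from limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation and fry; 1 entry was dropped because its name did not match its locus and 17 were kept by locus alone. The genes named were PHO1 everywhere, and per comparison the 10 largest increases and 10 largest decreases among called genes with a mean of at least 2 CPM in 1 group and no overlap between the libraries, plus up to 4 members of each list with the lowest adjusted p. With groups of 2 a lack of overlap often arises by chance. Counts adjusted over the list alone use Benjamini-Hochberg within 1 list, with no correction over the 29 lists or over the comparisons. Members of a list can vary together between libraries, so such a count is not that many separate results. The genes of the plot of phosphate transcripts, the phosphate starvation core genes in the tissue comparison and SEC3B in leaves were chosen after their values were seen. For genes with 3 or fewer reads in a group, reads are given in place of folds, except for PECP1 in the tissue comparison.

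The test was checked on counts simulated for KO against Compl from the real means, library sizes and dispersions, 10 times per setting. The 200 changed genes were drawn from those with a mean of at least 1 CPM, and each gene had 1 dispersion in all groups. So the recovery below does not cover lower genes, and no share covers groups that differ in spread. In roots (20441 to 20469 genes) 56% of genes changed 2-fold and 92.4% of those changed 4-fold were recovered, and in leaves (18347 to 18388 genes) 68.8% and 93.6%. The median estimated log2 fold changes were 0.99 and 2 in roots and 1 and 2 in leaves. False calls made up 9.96% and 8.29% of calls in roots and 11.6% and 9.78% in leaves, above the nominal 5%, so more of the called genes are false than the adjusted p states. A limit of 10% false calls had been set as a condition for the first simulation, was exceeded in 3 of its 4 settings, and was replaced by reporting the shares. With no gene changed, 0 to 2 genes were called in roots and 0 to 5 in leaves.

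The other settings tried, chosen at the same time, were DESeq2 1.42.0 size factors, library size alone, no filter on low counts, DESeq2, limma-voom, only the groups compared, all 16 libraries in 1 fit, the replicate number as a block, and leaving out each library in turn. For the matching of leaf to root groups they were a marker fold of at least 4 or at least 1 on the log2 scale, and Spearman's rho. Figures were drawn with matplotlib.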

Results

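Transcripts were counted in roots and leaves of Arabidopsis thaliana plants that differ at PHO1, the gene of the exporter that loads phosphate into the root xylem. The pho1-4 mutant (labelled KO) was compared with the mutant complemented with PHO1 (Compl) and with EXS32 and EXS34, 2 independent lines of the mutant that express the EXS domain of PHO1 fused to GFP. The plants were 25 days old. Each of the 4 genotypes was represented by 2 libraries per tissue, which gives 16 libraries in 8 groups. Reads assigned to genes numbered 20139794 to 31405117 per root library and 9465995 to 15530134 per leaf library. The labels do not say whether the 2 libraries of a group came from separate plants, so p-values measure only the spread between these libraries. The comparisons ask how loss of PHO1 changes the transcriptome of each organ, and which of these changes are absent when the EXS domain alone is present. Fold changes are log2 values with their standard error, and adjusted p-values of genes come from the quasi-likelihood test of edgeR. Levels are read counts scaled to library size (CPM) as mean ± SD with n = 2, or n = 4 where both EXS lines were averaged. An SD with n = 4 also holds the difference between the 2 lines. P-values of the EXS mean use only the spread within groups. Root Compl replicate 1 stood apart on the first principal component of the root libraries (40.9% of the variance), at 68.3 against 31.82 for Compl replicate 2 and -44.68 to 8.89 for the other 6.

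PHO1 (AT3G23430) lies on chromosome 3 at 8387398 to 8393467 in TAIR10.1. Its level in roots was 2079 ± 200.2 CPM in KO, 2601 ± 471.5 in Compl, 1888 ± 3.03 in EXS32 and 1917 ± 676 in EXS34. None of the 8 root comparisons called PHO1 (adjusted p from 0.223 to 0.975); KO against Compl gave a log2 fold change of -0.32 ± 0.25 (adjusted p = 0.514). Reads counted over the whole locus can come from the mutant transcript or from a transgene, so this count does not check the genotype labels. In leaves PHO1 stood at 62.0 ± 2.01 CPM in the libraries labelled KO, 93.2 ± 24.3 in those labelled Compl, 79.85 ± 10.7 in those labelled EXS32 and 53.9 ± 11.3 in those labelled EXS34. The libraries labelled EXS34 were lower than those labelled Compl (log2 fold change -0.78 ± 0.21, adjusted p = 0.0394). This call ended without replicate 2 labelled Compl (-0.49, adjusted p = 0.169) or replicate 2 labelled EXS34 (-0.56, adjusted p = 0.165), and when only these 4 libraries were fitted (adjusted p = 0.0943), when all 16 were (0.06) or with a replicate block (0.0529). The leaf files carry names that give another genotype than the sample labels, so leaf groups are named by their labels throughout. The genotype effect on PHO1 did not differ detectably between roots and leaves in any of the 6 pairwise comparisons (adjusted p from 0.36 to 0.961 for the interaction, with leaf groups as labelled). With the leaf groups named by their files, an alternative chosen after the data were seen, these ran from 0.0884 to 0.945 and the sign turned in 3 of the 6.

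**Figure D1:**
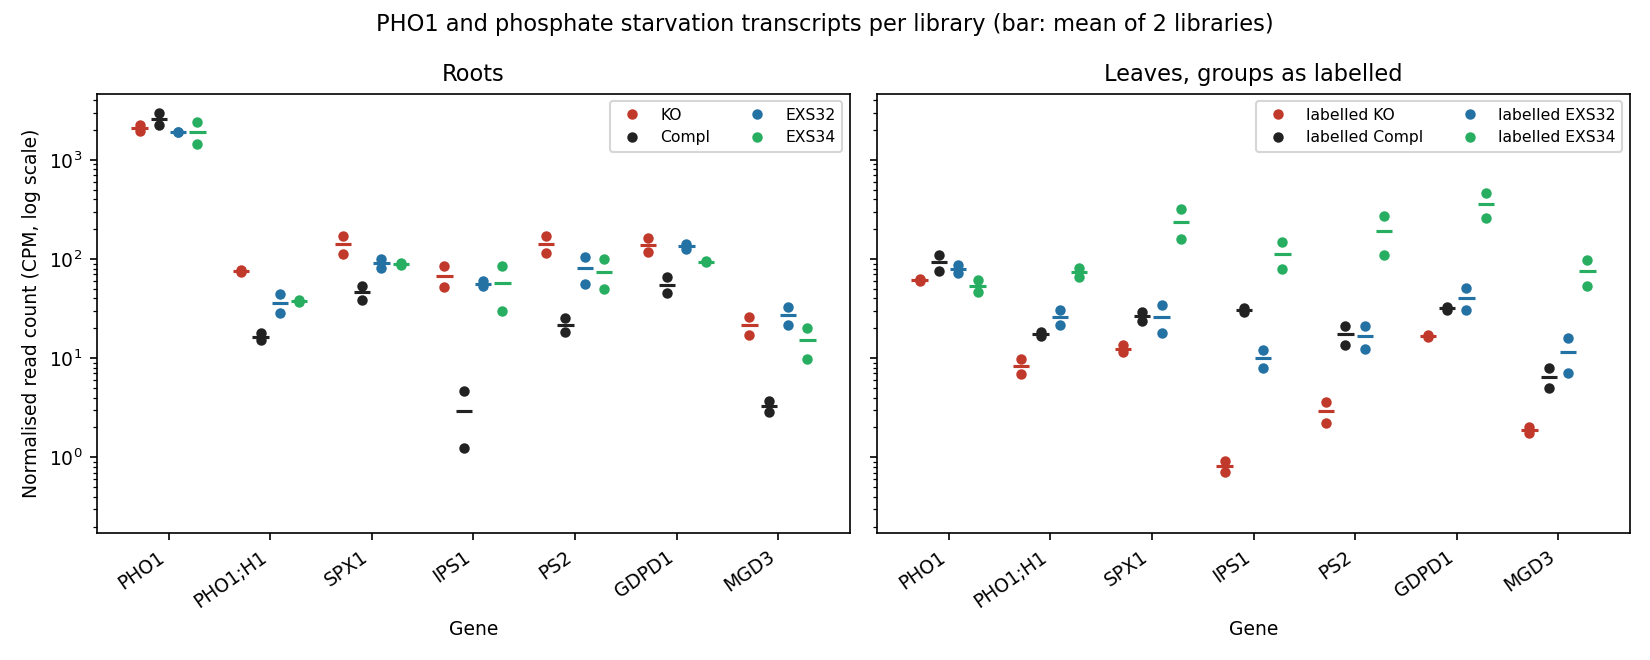
Normalised read counts (CPM, log axis) of PHO1 and 6 phosphate starvation transcripts in each root library (left) and leaf library (right, groups as labelled); points are libraries and bars are means of 2. IPS1 averaged 2.94 CPM in Compl roots and 56.3 to 67.8 CPM in the other root groups, and in leaves it was highest in the libraries labelled EXS34 (113 CPM).

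In roots, the mutant carried more phosphate starvation transcripts than the complemented line. Of the 15 measured members of the phosphate starvation core list, 7 were higher in KO and none lower; adjusted over the list alone 11 were higher and 1 lower. The noncoding RNA IPS1, a decoy for a microRNA of phosphate signalling, stood at 67.8 ± 22.9 CPM in KO and 2.94 ± 2.39 in Compl (log2 fold change 4.55 ± 0.69, adjusted p = 0.045). PHO1;H1, the closest homologue of PHO1, reached 74.98 ± 2.17 CPM against 16.4 ± 1.89, the sensor gene SPX1 141 ± 39.7 against 46.2 ± 10.3, and GDPD1, a glycerophosphodiester phosphodiesterase, 139 ± 31.7 against 55.2 ± 14.2. The phosphatase gene PECP1 had 102 and 116 reads in the KO libraries and 1 and 0 in the Compl libraries. Of 16 membrane lipid remodelling genes 4 were higher (7 higher and 1 lower adjusted over the list alone), among them SQD1 of sulfolipid synthesis (1.61 ± 0.19) and the galactolipid synthase MGD3 (2.72 ± 0.42). The phosphate transporter genes PHT1;8 and PHT1;3 were lower in KO, at 0.791 ± 0.109 against 10.03 ± 1.02 CPM and 99.2 ± 16.7 against 186 ± 15.9 CPM.

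Outside phosphate, the zinc exporter gene HMA2 (-1.18 ± 0.16) and the plastid ferredoxin reductase gene RFNR2 (-0.93 ± 0.11) were lower in KO roots, as was the cation exchanger gene CHX17 (-2.49 ± 0.35). The nitrate reductase gene NIA1 (1.41 ± 0.23), CYP79B3 of indole glucosinolate synthesis (1.22 ± 0.18) and the phloem sucrose transporter gene SUC2 (0.91 ± 0.14) were higher. The camera test with a preset correlation of 0.01 called 11 lists. Phosphate starvation core (adjusted p = 3.81e-07), membrane lipid remodelling (0.0043), photosynthesis (8.01e-05) and anthocyanin (0.00283) lay above other genes, and xylem and secondary wall (8.01e-05), root hair (0.00115), suberin (0.00395), heat shock (0.00777), root-enriched (0.0138), abscisic acid (0.0141) and zinc deficiency transcripts (0.0164) below. Each of these 11 calls was lost with an estimated correlation (adjusted p from 0.582 to 0.65, and 0.582 for the phosphate starvation core). Apart from 1 zinc deficiency gene, HMA2, no member of the last 7 lists, of photosynthesis or of anthocyanin was called over all genes; adjusted over the list alone 6 of 7 xylem, 5 of 10 root hair and 3 of 12 suberin genes were lower. Compl replicate 1, the library apart on the first component, was the higher of the 2 Compl libraries for every member of these 3 lists except the root hair gene RHD2 (78.3 against 84.9 CPM), at 116 against 79.5 CPM for CESA7, 149.9 against 95.2 for CESA4, 230 against 159 for XCP1, 283 against 193 for PRP3 and 125 against 40.4 for KCS2. The median log2 fold change of the lipid list was 0.77 as fitted and 0.22 when its 2 genes with 3 or fewer reads in a group were set to a floor of 3 reads.

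KO against Compl called 182 of 20597 genes in roots, 96 higher and 86 lower. With library size as the sole scaling the share of higher calls moved from 52.7% to 65.8%, but it was 38.2% with DESeq2, 41% with limma-voom, and 48% and 28.5% without Compl replicate 1 and 2. The count depended on single libraries: 0 genes were called without KO replicate 2, 5 without KO replicate 1, 25 without Compl replicate 1 and 1427 without Compl replicate 2. Fitting only these 4 libraries called 11 genes, limma-voom 78 and DESeq2 1221.

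**Figure D2:**
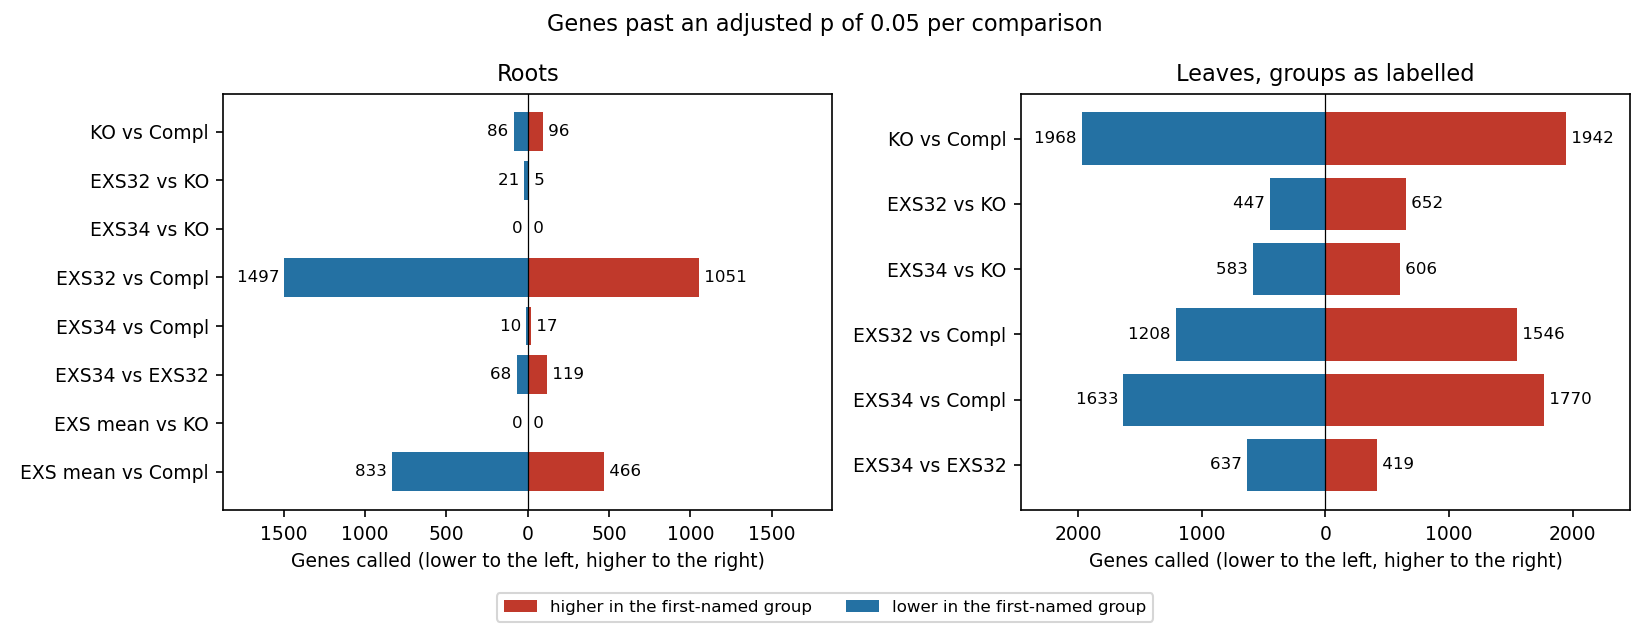
Genes past an adjusted p of 0.05 in each comparison, drawn to the right where higher and to the left where lower in the first-named group, for roots (left) and leaves as labelled (right). Root counts run from 0 for EXS34 against KO to 2548 for EXS32 against Compl, and leaf counts from 1056 to 3910.

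The EXS lines were then set against the mutant they derive from. In EXS32 roots 21 genes were lower than in KO and 5 higher. The aliphatic glucosinolate gene CYP79F2 fell from 186 ± 26.3 to 36.9 ± 6.05 CPM, the sulfate assimilation genes APR1 and APR2 from 126 ± 10.9 to 33.8 ± 5.28 and from 84.7 ± 3.65 to 31.9 ± 2.12, and the nicotianamine synthase gene NAS1 from 61.9 ± 2.05 to 15.3 ± 0.0335. The cytokinin response genes ARR7 (-1.73 ± 0.14) and ARR6 (-1.43 ± 0.18), the ammonium transporter gene AMT1;2 (-1.74 ± 0.14) and IPMI2 of methionine chain elongation (-1.55 ± 0.17) were also lower. Of the 5 genes that were higher, the galactosidase genes BGAL1 and BGAL2 rose by 1.72 ± 0.14 and 1.22 ± 0.15, and the other 3 were GDH1, the polyol transporter gene PMT6 and the exocyst gene SEC3B. SEC3B has a paralogue, SEC3A, next to it, and whether reads were shared between them was not examined.

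By list, 1 of 16 glucosinolate genes, 2 of 13 sulfate deficiency genes, 1 of 23 iron deficiency genes and 2 of 9 cytokinin genes were lower in EXS32 than in KO over all genes. Adjusted over the list alone these numbers were 13, 10, 8 and 5. Camera called 12 lists, led by glucosinolate (adjusted p = 2.74e-11), sulfate deficiency (1.07e-10) and iron deficiency (6.39e-10). Each of the 12 was lost with an estimated correlation (adjusted p = 0.487 for these 3). For some iron deficiency genes KO replicate 1 lay far above KO replicate 2, at 341.6 against 120.1 CPM for FRO2 and 302.6 against 134.4 for IRT1. For others, such as NAS1 (63.3 against 60.41), it did not. EXS32 against KO called 26 genes, 5 higher and 21 lower, and 0 or 1 when any of its 4 libraries was left out; the gene called without KO replicate 1 was not among the 26. Fitting only the 4 libraries called 517 genes and DESeq2 537, of which 41.8% and 32% rather than 19.2% were higher.

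EdgeR called 0 genes for EXS34 against KO in roots, with 1871 at an unadjusted p under 0.05, limma-voom 0, DESeq2 97 and the fit of all 16 libraries 43. For the mean of EXS32 and EXS34 against KO edgeR called 0, with 1627 at an unadjusted p under 0.05, limma-voom 0, DESeq2 176 and the fit of all 16 libraries 35. PHO1;H1 averaged 37.0 ± 6.53 CPM over the 4 EXS libraries against 74.98 ± 2.17 in KO (-1.02 ± 0.16, adjusted p = 0.262), and NAS1 25.7 ± 12.5 against 61.9 ± 2.05 (adjusted p = 0.112). In EXS34 the anthocyanin list had a median log2 fold change of 2.42 over KO, with 13 of 15 members past the threshold adjusted over the list alone (camera adjusted p = 2.06e-12, and adjusted p = 0.673 with an estimated correlation). Camera called the phosphate starvation core below other genes for EXS34 and for EXS32 against KO (adjusted p = 0.00256 and 0.024), which was lost with an estimated correlation (adjusted p = 0.673 and 0.637). Their medians were -0.43 and -0.29, with 0 of 15 genes called over all genes by edgeR and 1 lower in each when adjusted over the list alone.

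The mean of both EXS lines was also set against the complemented line. Of the 15 phosphate starvation core genes 7 were higher and none lower (10 higher and 2 lower adjusted over the list alone). IPS1 averaged 56.9 ± 22.9 CPM over the 4 EXS libraries against 2.94 ± 2.39, MGD3 21.2 ± 9.42 against 3.28 ± 0.599, PHO1;H1 37.0 ± 6.53 against 16.4 ± 1.89, GDPD1 114 ± 24.6 against 55.2 ± 14.2 and SPX1 90.06 ± 8.08 against 46.2 ± 10.3. Of 16 lipid remodelling genes 6 were higher, SQD1 by 1.09 ± 0.17. PHT1;8 (-3.004 ± 0.36), PHT1;3 (-0.80 ± 0.11) and PHO2, whose product degrades phosphate transporters (-1.75 ± 0.35), were lower.

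In the same comparison 8 of 13 sulfate deficiency genes were lower, including LSU2 (-1.66 ± 0.26), SDI1 (-2.65 ± 0.46) and APR2 (-0.85 ± 0.14). Of 23 iron deficiency genes 4 were lower, among them NAS1 (-1.77 ± 0.16), NAS2 (-2.01 ± 0.35) and IRT2 (-1.69 ± 0.26). Suberin, the lipid polymer of root barriers, had 4 of 12 genes lower, with ASFT at 74.3 ± 23.8 against 202 ± 55.7 CPM and KCS2 at 22.7 ± 13.4 against 82.6 ± 59.7. Xylem and secondary wall genes were lower in 5 of 7 cases, including the cellulose synthase gene CESA7 (-0.67 ± 0.14) and the protease gene XCP1 (-0.74 ± 0.16), and root hair genes in 3 of 10, including EXPA18 (-0.82 ± 0.11) and PRP3 (-1.02 ± 0.14). Photosynthesis genes were higher in 4 of 23 cases, such as LHCB4.2 (1.62 ± 0.21) and LHCA1 (1.28 ± 0.24), and anthocyanin genes in 3 of 15. These means hide differences between the lines: DFR stood at 3.44 ± 3.37 CPM in EXS32 and 27.2 ± 0.1915 in EXS34, against 0.645 ± 0.191 in Compl and 2.89 ± 1.93 in KO, and APR2 at 31.9 ± 2.12 in EXS32 and 64.65 ± 2.46 in EXS34, against 81.95 ± 21.5 in Compl and 84.7 ± 3.65 in KO. Without Compl replicate 1 the calls of CESA7 (-0.36, adjusted p = 0.125), XCP1 (-0.44, adjusted p = 0.158), EXPA18 (-0.66, adjusted p = 0.052), KCS2 (-0.99, adjusted p = 0.0896), NAS2 (-1.07, adjusted p = 0.0501) and IRT2 (-1.12, adjusted p = 0.0501) ended, and those of ASFT, PRP3 and NAS1 did not. The calls of PHO2, LHCA1 and DFR ended when either Compl library was left out. Camera called 15 lists, among them photosynthesis (adjusted p = 4.05e-09), iron deficiency and anthocyanin (1.96e-06 each), sulfate deficiency (4.31e-05), phosphate starvation core (6.93e-05) and suberin (0.000167). The adjusted p with an estimated correlation was 0.436 for the first 5 and 0.438 for suberin. Adjusted over the list alone, 9 sulfate deficiency, 9 iron deficiency, 6 suberin, 6 xylem and 6 root hair genes were lower, and 8 lipid remodelling, 14 photosynthesis and 12 anthocyanin genes higher.

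The mean of both lines against Compl called 1299 genes, 466 higher and 833 lower; with library size as the sole scaling 47.6% rather than 35.9% were higher. The count was 539 without Compl replicate 1 and 2409 without Compl replicate 2, and between 95 and 776 without one of the 4 EXS libraries, with 53.2% higher without EXS32 replicate 1. EXS32 against Compl called 2548 genes, with APR1 (-2.10 ± 0.23), CYP79F2 (-2.35 ± 0.23), ARR7 (-1.41 ± 0.14) and NAS1 (-2.39 ± 0.20) lower; it called 1617 without Compl replicate 1, 1337 from these 4 libraries alone, and 167 and 112 without EXS32 replicate 1 and 2, where 65.9 and 59.8% were higher rather than 41.2%. EXS34 against Compl called 27. NIA1 (1.98 ± 0.24), PSBQ-2 of photosystem II (1.97 ± 0.22), PMT6 (1.70 ± 0.11) and SEC3B (1.82 ± 0.20) were higher there, and AMT1;2 (-1.18 ± 0.13), the fasciclin-like FLA11 (-1.06 ± 0.12) and the proton pump gene HA7 (-0.93 ± 0.11) lower. Without EXS34 replicate 1 or 2 that count was 0 or 4, without Compl replicate 1 or 2 it was 6 or 698, fitting only these 4 libraries called 3, none of them among the 27, and DESeq2 called 632; 63% of the 27 were higher, but 24.8% of the 698 and 44.5% of the 632. In EXS34 the photosynthesis list had a median of 1.82 over Compl and the anthocyanin list of 4.18, with 21 of 23 and 13 of 15 genes past the threshold adjusted over the list alone and none over all genes. Camera gave these lists adjusted p = 1.5e-16 and 4.94e-14, and adjusted p = 0.452 with an estimated correlation for both.

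**Figure D3:**
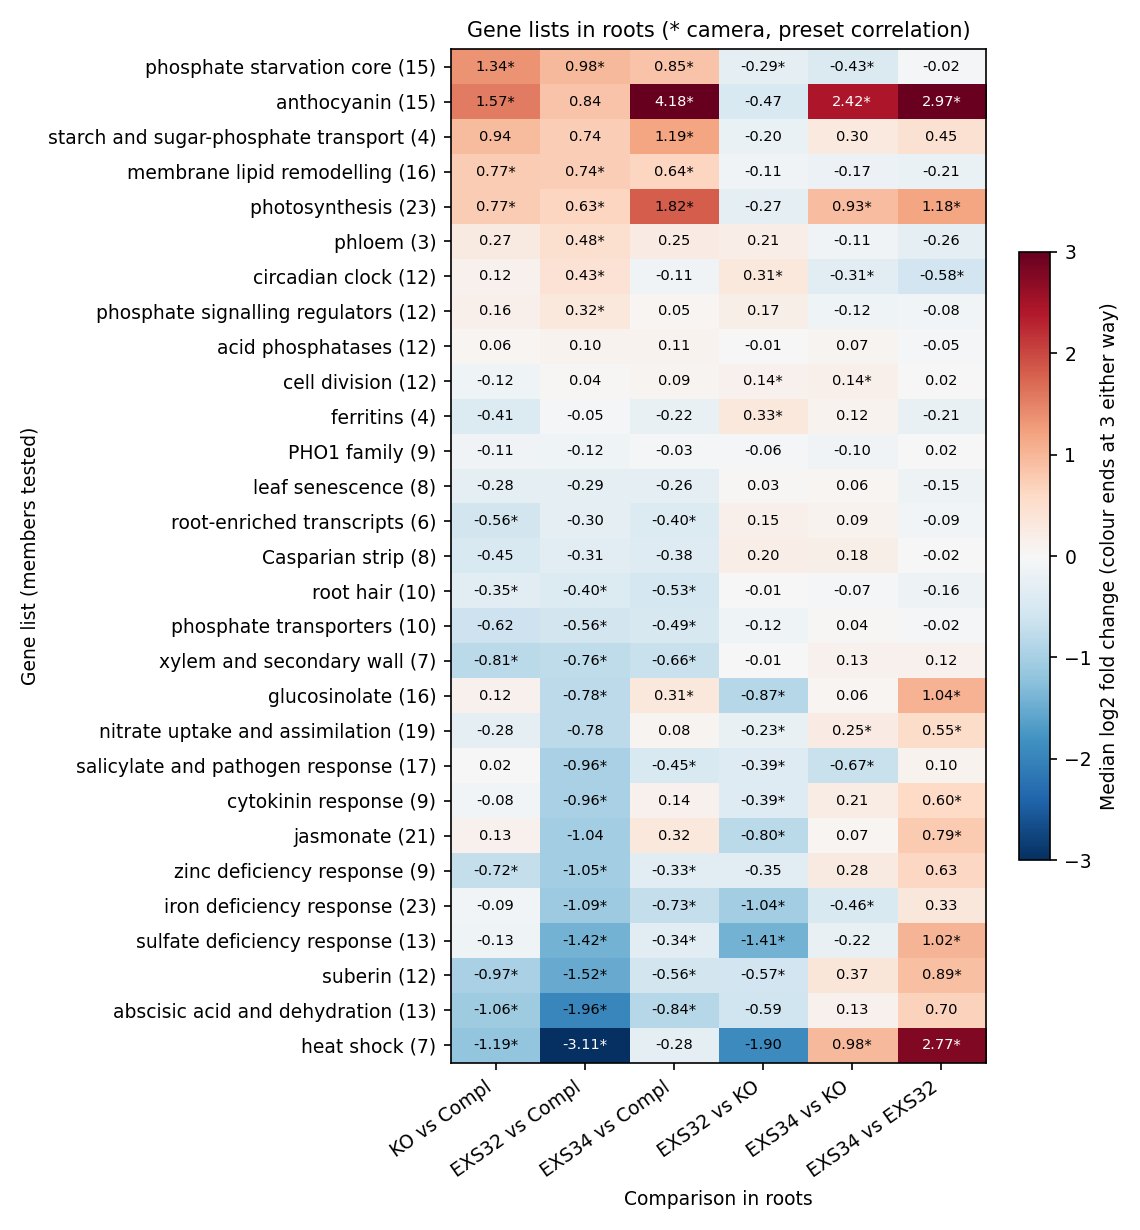
Median log2 fold change of each of the 29 gene lists in the 6 pairwise root comparisons (colour and number), with the number of members tested in parentheses and an asterisk where camera with a preset correlation called the list. The phosphate starvation core had medians of 1.34, 0.98 and 0.85 for KO, EXS32 and EXS34 against Compl; none of the asterisks held with an estimated correlation.

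The 2 EXS lines also differed from each other in roots. EXS34 had more transcript than EXS32 for 9 of 16 glucosinolate genes, among them CYP79F2 (162 ± 12.9 against 36.9 ± 6.05 CPM), SOT17 (1.82 ± 0.24) and UGT74B1 (1.202 ± 0.13). Sulfate deficiency genes were higher in 3 of 13 cases, including APR1 (2.08 ± 0.23) and APR2 (1.02 ± 0.17), and cytokinin response genes in 3 of 9, namely ARR5, ARR6 and ARR7 (1.39 ± 0.15, 1.64 ± 0.18 and 1.79 ± 0.14). Adjusted over the list alone 11 glucosinolate genes were higher and 1 lower, and 9 sulfate deficiency and 5 cytokinin response genes higher. The nitrate transporter gene NRT1.1 stood at 821 ± 173 against 223 ± 10.3 CPM and NAS1 at 36.1 ± 6.11 against 15.3 ± 0.0335. Lower in EXS34 were DIN10, a dark-inducible raffinose synthase gene (285 ± 37.7 against 1125 ± 157 CPM), UMAMIT20 (-1.63 ± 0.16), the clock gene PRR9 (-1.92 ± 0.29) and the expansin gene EXPA7 (-0.68 ± 0.10). EXS34 against EXS32 called 187 genes, 119 higher and 68 lower. It called 0 without EXS34 replicate 2 or either EXS32 library, 15 without EXS34 replicate 1, and 1072 by DESeq2. Camera called 10 lists, anthocyanin (median 2.97, adjusted p = 1.41e-10) and glucosinolate (9.47e-10) first, each with adjusted p = 0.444 with an estimated correlation.

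Across all 8 root comparisons camera did not call the lists PHO1 family, acid phosphatases, Casparian strip and leaf senescence; the lowest adjusted p was 0.0581, for Casparian strip. In leaves 11 lists were called in no comparison, which were those of iron deficiency, zinc deficiency, ferritins, suberin, Casparian strip, xylem, phloem, root-enriched transcripts, cell division, the circadian clock and the PHO1 family (lowest adjusted p = 0.0701).

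Because the names of the leaf files and the leaf labels disagree, the leaf groups were matched to the root groups on marker genes chosen from roots alone. The 59 markers differed between root groups at an adjusted p under 0.01 with a log2 fold change of at least 2, and reached 1 CPM in leaves. Of the 24 ways of pairing 4 leaf groups with 4 root groups, the pairing by labels had the lowest summed correlation, -1.32, and ranked 24. The highest sum, 2.45, paired KO roots with the leaves labelled EXS34, Compl roots with those labelled KO, EXS32 roots with those labelled Compl and EXS34 roots with those labelled EXS32, which is the pairing that the file names give; the next sum was 1.52. The correlations are across genes, which are not independent replicates. The pairs of leaf libraries are the same under either naming, and each direction in the leaf comparisons follows the labels.

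**Figure D4:**
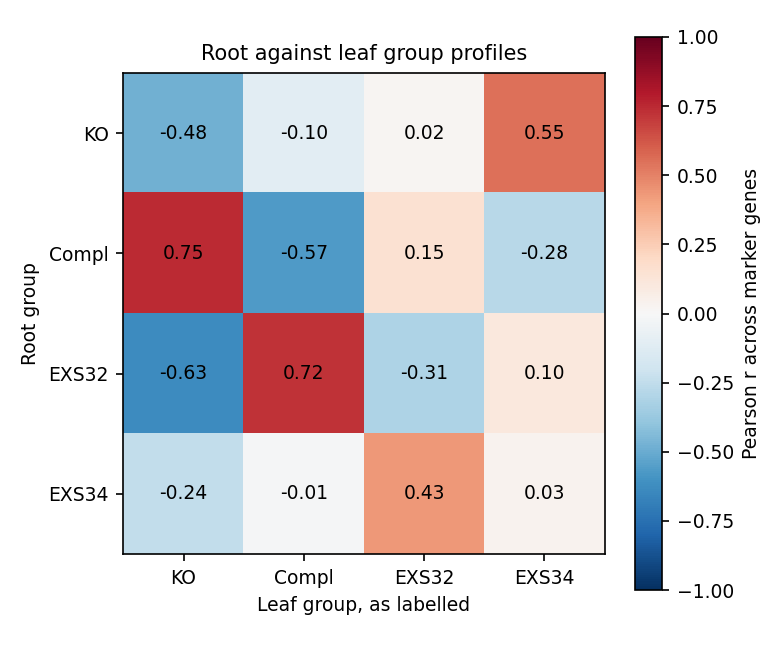
Pearson r across the 59 root-chosen marker genes between each root group (down) and each leaf group as labelled (across), after centring each gene within its tissue. The diagonal, which pairs equal labels, runs from -0.57 to 0.03, and the highest value for each root group lies off it, at 0.55, 0.75, 0.72 and 0.43.

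The leaf libraries labelled EXS34 carried more phosphate starvation transcripts than those labelled KO. The file names call these groups KO and Compl. As labelled, 14 of 15 core genes were higher (15 adjusted over the list alone), with a list median of 4.26. IPS1 stood at 113 ± 49.3 against 0.814 ± 0.135 CPM, the related AT4 at 235 ± 35.8 against 9.71 ± 0.499, SPX1 at 238 ± 112 against 12.5 ± 1.37, SPX3 at 27.5 ± 17.0 against 0.522 ± 0.279 and PHO1;H1 at 73.7 ± 11.5 against 8.29 ± 1.99. Lipid remodelling genes were higher in 13 of 16 cases (15 adjusted over the list alone), among them GDPD1 (4.43 ± 0.39), MGD2 (4.201 ± 0.40), PLDZ2 (4.08 ± 0.31) and SQD1 (2.24 ± 0.17). Acid phosphatases were higher in 9 of 12 cases, including PAP17 (2.93 ± 0.28), and phosphate transport genes in 4 of 6 (9 and 4 adjusted over the list alone), including PHT1;4 (2.87 ± 0.44) and PHF1, which moves transporters to the membrane (1.68 ± 0.20). The cold response gene COR15A was higher (1.70 ± 0.15), and NRT1.1 (-1.35 ± 0.15) and the glucosinolate gene SOT18 (-0.86 ± 0.13) were lower. This comparison called 1189 of 18548 genes, 606 higher and 583 lower, but 144 and 143 without replicate 1 and 2 labelled KO, and 371 from these 4 libraries alone. A replicate block gave 1949 calls. Camera called 7 lists, the core with adjusted p = 2.61e-20, with adjusted p = 0.259 with an estimated correlation. By fry the core had adjusted p = 0.0231.

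The libraries labelled EXS34 also lay above those labelled EXS32 and Compl in these transcripts. By file name these groups are, in the same order, KO, EXS34 and EXS32. Against the label EXS32, 13 of 15 core genes and 11 of 16 lipid remodelling genes were higher and none lower (15 and 14 higher adjusted over the list alone), with IPS1 (3.50 ± 0.37), SPX1 (3.19 ± 0.44), GDPD1 (3.14 ± 0.36), PAP17 (1.85 ± 0.26), PHO1;H1 (1.5 ± 0.20), PHF1 (1.42 ± 0.21) and SQD1 (1.303 ± 0.17). The pathogenesis-related gene PR2 was higher (3.72 ± 0.64) and NRT1.1 lower (-1.41 ± 0.15). That comparison called 1056 genes, 419 higher and 637 lower, and 1840 with a replicate block. It called 165 and 527 without replicate 1 and 2 labelled EXS32, 414 and 1663 without replicate 1 and 2 labelled EXS34, and 158 from these 4 libraries alone. The share of higher calls was 39.7%, but 52.9 and 58.1% without replicate 1 and 2 labelled EXS34 and 51.8% with all 16 libraries in 1 fit. Camera called 10 lists, the core with adjusted p = 3.63e-15 and adjusted p = 0.491 with an estimated correlation. By fry the core had adjusted p = 0.0619.

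Against the label Compl, 13 of 15 core genes, 12 of 16 lipid remodelling genes, 11 of 15 anthocyanin genes and 15 of 18 glucosinolate genes were higher in the libraries labelled EXS34. PHO1;H1 (2.08 ± 0.20), PAP17 (2.73 ± 0.28), SPX3 (4.02 ± 0.59), the anthocyanin gene UGT75C1 (2.26 ± 0.21) and CYP79F1 (2.14 ± 0.14) were among them. Adjusted over the list alone 15 core, 13 lipid remodelling, 12 anthocyanin and 15 glucosinolate genes were higher, and 1 glucosinolate gene lower. Photosynthesis genes were lower in 19 of 26 cases and higher in 3 (20 and 3 adjusted over the list alone), with LHCA1 at 2529 ± 119 against 4740 ± 129 CPM and LHCB2.3 at 178 ± 38.6 against 529 ± 17.41; members of the LHCB1 and RBCS families share sequence, so single counts there are uncertain. ARR6 was lower (-1.45 ± 0.28). For the labels EXS34 and Compl the file names give KO and EXS32. This comparison called 3403 genes, 1770 higher and 1633 lower, 1300 (46.8% higher rather than 52%) and 1022 without replicate 1 and 2 labelled Compl, and 1918 from these 4 libraries alone. Camera called 13 lists, the core with adjusted p = 1.21e-10, with adjusted p = 0.442 with an estimated correlation.

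As labelled, 4 of 15 phosphate starvation core genes were lower in the leaves labelled KO than in those labelled Compl and none higher (5 lower adjusted over the list alone). The file names call these groups Compl and EXS32, so by them this is not a comparison of the mutant. IPS1 stood at 0.814 ± 0.135 against 30.5 ± 1.99 CPM, AT4 at 9.71 ± 0.499 against 162 ± 31.6, PHO1;H1 at 8.29 ± 1.99 against 17.5 ± 1.14 and PECP1 at 0.97 ± 0.558 against 8.60 ± 1.90, while PHF1 (14.67 ± 0.901 against 10.82 ± 1.397) and SPX2 (21.17 ± 3.39 against 17.41 ± 0.739) were not called. Glucosinolate genes were higher in 14 of 18 cases, with CYP79F1 at 404 ± 39.5 against 61.2 ± 10.6 CPM, SUR1 (1.52 ± 0.11) and BCAT4 (1.38 ± 0.12). Sulfate deficiency genes were higher in 7 of 12 cases and lower in 1, with LSU2 at 15.5 ± 6.28 against 1.53 ± 0.193 CPM. Photosynthesis genes were lower in 20 of 26 cases and higher in 6, with LHCA1 (-1.22 ± 0.07), LHCB3 (-1.17 ± 0.08) and LHCB2.3 (-2.28 ± 0.14). Adjusted over the list alone 15 glucosinolate genes were higher and 1 lower, 9 sulfate deficiency genes higher and 1 lower, and 20 photosynthesis genes lower and 6 higher. The jasmonate gene JAZ7 was higher (4.71 ± 0.30), and the asparagine synthetase gene ASN1 (-3.79 ± 0.27) and ARR6 (-2.25 ± 0.29) were lower. This comparison called 3910 genes, 1942 higher and 1968 lower; it called 1556 and 1522 without replicate 1 and 2 labelled KO, and 2051 and 1489 without replicate 1 and 2 labelled Compl, with 50.4 to 58.9% rather than 49.7% higher. Camera called 8 lists, among them glucosinolate (adjusted p = 1.86e-10), photosynthesis (1.87e-05) and the core (0.00204), with adjusted p = 0.173, 0.254 and 0.715 with an estimated correlation. Fry gave these lists adjusted p = 0.000879, 0.000894 and 0.089.

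The leaves labelled EXS32 lay above those labelled KO in anthocyanin and some phosphate starvation transcripts. Their file names read EXS34 and Compl. As labelled, 9 of 15 anthocyanin genes were higher (13 adjusted over the list alone), with chalcone synthase CHS at 92.4 ± 15.1 against 29.2 ± 0.153 CPM and DFR at 31.0 ± 11.8 against 8.87 ± 1.97. Of the 15 core genes 3 were higher (7 adjusted over the list alone), IPS1 (3.60 ± 0.58), AT4 (3.13 ± 0.22) and PHO1;H1 (1.66 ± 0.22), and MGD2 was higher as well (2.15 ± 0.41). The pathogenesis-related gene PR1 was lower, at 47.3 ± 5.90 against 412 ± 162 CPM. This comparison called 1099 genes, 652 higher and 447 lower. It called 1716 from these 4 libraries alone, of which 46% rather than 59.3% were higher, and 2153 with a replicate block, of which 49.9% were. It called 39 and 92 without replicate 1 and 2 labelled KO, and 459 and 304 without replicate 1 and 2 labelled EXS32. Camera called 9 lists, anthocyanin with adjusted p = 1.57e-08 and the core with 8.07e-07, both with adjusted p = 0.581 with an estimated correlation. Fry gave them adjusted p = 0.029 and 0.134.

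Against the label Compl, the leaves labelled EXS32 had 12 of 15 anthocyanin and 14 of 18 glucosinolate genes higher, with CHS (2.02 ± 0.18), UGT75C1 (2.51 ± 0.20) and CYP79F1 (2.37 ± 0.14). By file name the groups labelled EXS32 and Compl are EXS34 and EXS32. Sulfate deficiency genes were higher in 5 of 12 cases, including APR1 (2.35 ± 0.37) and LSU2 (3.39 ± 0.48). Photosynthesis genes were lower in 17 of 26 cases and higher in 5, with LHCA4 at -0.73 ± 0.07 and RBCS2B at 0.86 ± 0.08. Adjusted over the list alone 14 anthocyanin, 15 glucosinolate and 9 sulfate deficiency genes were higher, and 19 photosynthesis genes lower and 5 higher. IPS1 (-1.60 ± 0.37) and AT4 (-0.93 ± 0.19) were lower. This comparison called 2754 genes, 1546 higher and 1208 lower. It called 986 and 1171 without replicate 1 and 2 labelled Compl, and 1525 and 1794 without replicate 1 and 2 labelled EXS32. Camera called 7 lists, anthocyanin with adjusted p = 4.39e-12 and glucosinolate with 3.87e-11, with adjusted p = 0.243 and 0.162 with an estimated correlation.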

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

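The tests of leaf tissue in root samples, the tissue comparisons of the phosphate starvation core genes and the naming of leaf groups by file were chosen after the results were seen; the matching of leaf to root groups and the tissue comparison of PHO1 were planned.

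The difference between roots and leaves, as labelled, was tested as an interaction in 1 edgeR fit of all 16 libraries. That fit gives each gene 1 spread in both tissues. For KO against Compl it called 1121 root genes rather than 182, and 3208 leaf genes rather than 3910. Its p-values may thus understate the spread between root libraries. Values are given for the comparisons in which camera called the core list in both tissues in opposite directions. That choice favours differences in the same genes, so the counts below are no separate support for one. For KO against Compl, 9 of 15 core genes differed between the tissues (adjusted p from 3.85e-05 to 0.0352). The root minus leaf differences (log2) were 9.76 for IPS1, 5.27 for PS2, 5.2 for AT4, 4.49 for MGD3, 4.35 for SPX3, 3.28 for PHO1;H1, 2.71 for SPX1 and 2.26 for GDPD1. PECP1 had 1 read in all in the Compl root libraries, so its fitted value, 9.91, is no bound. For EXS32 against KO the difference was -3.56 for AT4 and -2.69 for PHO1;H1 (adjusted p = 0.000881 and 0.00441). For EXS34 against KO, 14 of 15 differed (adjusted p from 6.76e-05 to 0.0147). The values were -8.4 for PECP1, -7.34 for IPS1, -6.96 for PS2, -6.75 for SPX3, -5.85 for MGD3, -5 for both AT4 and GDPD1, -4.92 for SPX1 and -4.14 for PHO1;H1. The others were -3.36 for PAP17, -2.69 for PHT1;4, -2.59 for SQD2, -2.02 for SPX2 and -1.61 for PHF1.

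In roots 7 of the 15 core genes were higher in KO than in Compl and in leaves, as labelled, 4 were lower, and the leaf file names give another genotype than the labels. Mislabelled leaf libraries are a candidate explanation: the pairing of leaf with root groups by labels ranked 24 of 24, and its summed r lay 3.78 below that of the best pairing, which is the one the file names give and was best in all 3 alternatives too, of which 1 rests on only 5 markers rather than 59. If the labels were right, the pairing by labels had been predicted to rank 1, so this test argues against the labels. With the leaf groups named by their files, 13 of 15 core genes had the same sign in both tissues for KO against Compl, IPS1 with 4.56 in roots and 7.10 in leaves. Of the 15, 8 still differed between the tissues, 6 of them with the same sign in both. For EXS34 against KO 0 rather than 14 differed. For EXS32 against KO 7 rather than 2 differed, 5 of them with the same sign in both. For EXS34 against EXS32 0 rather than 12 differed, but only 7 of 15 had the same sign. The markers are not independent of the phosphate starvation genes. Each interaction test takes a naming as given, so it cannot separate wrong labels from a genotype effect that differs between the organs. Such an effect stays open.

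In EXS34 roots, photosynthesis transcripts were higher than in Compl and anthocyanin transcripts higher than in EXS32 by the preset camera test (adjusted p = 0.452 and 0.444 with an estimated correlation, and no member of either list called over all genes). Leaf tissue in these root samples could raise both, but would raise each transcript by 1 share of its leaf level. The implied shares of 26 photosynthesis transcripts had a ratio of upper to lower quartile of 5.41 and 4.04 in EXS34 replicates 1 and 2. In the same order LHCA1 needed 0.366 and 0.355%, and RBCS2B, at 2190 CPM in leaves, 0.00785 and 0.00175%. The anthocyanin transcripts needed a median share 373 and 341 times that of the photosynthesis transcripts, which argues against leaf tissue as their source. For photosynthesis the quartile ratios passed the limit set for arguing against leaf tissue as the whole cause. Most of the lowest shares were of LHCB1 and RBCS genes, whose single counts are uncertain because the families share sequence. So the spread of shares does not decide whether leaf tissue is the cause. A small admixture stays open, and a response of the root itself was not tested.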

How the results depend on the processing

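Of the 154 named gene values, 140 were called. Under alternatives other than leaving out a library, 146 kept their direction and their side of the threshold with DESeq2 size factors, 152 with library size alone, 142 without a filter, 151 with DESeq2, 132 with limma-voom, 145 in 1 fit of all 16 libraries, 123 with only the groups compared and 130 with the replicate block. With 1 library left out, 361 of 672 values did, 307 lost their call and 1 gained one; the lone library was assumed to vary like the other groups. The values that reversed were of PHO1, uncalled in each case. In roots EXS34 against EXS32 was 0.022 in the main fit, -0.021 with limma-voom, and -0.393 and 0.334 without EXS34 replicate 1 and 2. The EXS mean against KO was -0.128 in the main fit, and -0.335 and 0.036 without these. In leaves EXS32 against Compl was -0.22 in the main fit, and -0.468 and 0.072 without replicate 1 and 2 labelled Compl. The values -0.021, -0.393, 0.036 and 0.072 are the reversed ones. Of the 155 list calls, 153 held with DESeq2 size factors, 148 with the replicate block, 33 with fry and 0 with an estimated correlation. Depth limits low transcripts most in leaves. The cause was not tested for any value below.

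Genes called in roots are given in the order KO against Compl, EXS32 against KO, EXS34 against KO, EXS32 against Compl, EXS34 against Compl, EXS34 against EXS32, EXS mean against KO and EXS mean against Compl, leaving out those within 1.5 times. DESeq2 called 1221, 537, 97, 632 (EXS34 against Compl), 1072, 176 and 2411. All 16 libraries in 1 fit called 1121, 293, 43, 3845, 408, 1058, 35 and 2644. Only the groups compared called 11, 517, 1337 (EXS32 against Compl), 3 (EXS34 against Compl) and 5 (EXS mean against KO). No filter called 54 (EXS32 against KO), 71 (EXS34 against Compl) and 10 (EXS mean against KO). Limma-voom called 78 for KO against Compl and 2 for EXS34 against Compl, and DESeq2 size factors 5 for the latter. The replicate block called 104 for KO against Compl and 63 for EXS32 against KO. In leaves, as labelled, the replicate block called more genes in all 6 comparisons, with 2153 for EXS32 against KO, 1949 for EXS34 against KO and 1840 for EXS34 against EXS32. Deviations of equal replicate numbers correlated by -0.251 to 0.219 in roots and 0.036 to 0.335 in leaves. All 6 leaf correlations were positive and 4 were over 0.1, so whether the leaf libraries share more than a number stays open. Only the groups compared called 1716 for EXS32 against KO, 371 for EXS34 against KO, 1918 for EXS34 against Compl and 158 for EXS34 against EXS32, and all 16 libraries in 1 fit 682 and 712 for EXS32 and EXS34 against KO.

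Leaving out 1 library gave ranges, in roots in the same order, of 0 to 1427, 0 to 1, 0 to 1, 112 to 3302, 0 to 698, 0 to 15, 0 to 1 and 95 to 2409. In leaves they were 1489 to 2051 for KO against Compl, 39 to 459 for EXS32 against KO, 143 to 1149 for EXS34 against KO, 986 to 1794 for EXS32 against Compl, 1022 to 2917 for EXS34 against Compl and 165 to 1663 for EXS34 against EXS32. Lists called with an estimated correlation numbered 0 in all 14 comparisons. With fry they numbered 0 in roots except 8 for EXS32 against Compl and 4 for EXS34 against EXS32, and in leaves 2 for KO against Compl, 2 for EXS32 against KO, 3 for EXS32 against Compl and 0 for EXS34 against EXS32. The fry counts for leaf EXS34 against KO and against Compl are left out. For EXS34 against KO fry kept the core, lipid remodelling, acid phosphatase, anthocyanin, glucosinolate and heat shock lists (adjusted p = 0.0231 each). It lost phosphate transporters (0.0556). The best pairing of leaf with root groups was the same in all 3 alternatives, and the pairing by labels ranked 24, 24 and 23. With leaf groups named by their files, an alternative chosen after the data were seen, the PHO1 difference between tissues reversed, uncalled, for KO against Compl (-0.104), EXS34 against KO (-0.677) and EXS34 against Compl (-0.78). The core genes that differed between tissues then numbered 7 rather than 2 for EXS32 against KO, 0 rather than 14 for EXS34 against KO, 1 rather than 5 and 7 for EXS32 and EXS34 against Compl, and 0 rather than 12 for EXS34 against EXS32. With library size alone the median of all genes lay at most 0.0653 from 0 in any comparison. The PHO1 level in EXS32 roots was 1896 CPM by library total.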

Other observations

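The exocyst gene SEC3B, chosen after its values were seen, was measured at 7.68 and 5.59 CPM in KO roots, 5.87 and 6.76 in Compl, 20.6 and 24.1 in EXS32 and 24.65 and 20.1 in EXS34. In leaves it stood at 1.82 and 1.51 CPM in the libraries labelled KO, 5.34 and 5.34 in those labelled Compl, 5.34 and 5.72 in those labelled EXS32 and 1.27 and 0.891 in those labelled EXS34. Its neighbour and paralogue SEC3A lay between 64.9 and 78.5 CPM in all root libraries and between 43.3 and 54.0 CPM in all leaf libraries. By edgeR SEC3B was lower in the leaves labelled KO than in those labelled Compl (log2 fold change -1.67 ± 0.25, adjusted p = 0.00204). It was also lower in those labelled EXS34 than in those labelled EXS32 (-2.32 ± 0.28, adjusted p = 0.00498). In roots it was high in both EXS groups, and in leaves in the groups that the file names call EXS32 and EXS34. The leaf values thus follow the file names rather than the labels. As the gene was picked for its values, it is no separate test of the labels.

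Some acid phosphatase transcripts were near 0 in 1 group and not in others. In roots PAP25 had 0 and 0 reads in Compl, 12 and 27 in KO, 8 and 25 in EXS32 and 2 and 23 in EXS34. In leaves PAP24 had 1 and 0 reads in the libraries labelled KO, 9 and 17 in those labelled Compl, 12 and 16 in those labelled EXS32 and 211 and 97 in those labelled EXS34.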
